A study of Solanum lycopersicum with 30 samples.

How the data were processed

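Messenger RNA ratios were measured on 30 two-colour arrays that compared 20 RNA extracts of tomato (Solanum lycopersicum). The extracts fall into 10 states, which are controls, mock-inoculated plants at 3 and 7 days post inoculation (dpi) and virus-inoculated plants at 3 and 7 dpi, each in a susceptible and a resistant genotype, with 2 extracts per state. Per the labels, whiteflies acquired the virus for 48 h, 10 insects were caged on each plant for 12 h, 20 plants of each genotype were inoculated, and mock plants received insects without virus. Plants were treated with an insecticide (imidacloprid) when the cages were removed. The labels give the controls only as not infected, so age, caging, insecticide and handling of the controls are not given in the sources used here, and mock plants over controls can hold any of these beside whitefly feeding. The labels do not say whether the extracts of a state came from separate plants, so part of the spread between extracts may be technical. P-values rest on each clone's residual spread over all arrays and on a ratio of extract variance to array variance pooled over clones. They do not rest on a separate measure of each clone's spread between extracts. The tissue extracted is not given in the sources used here.

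The deposited values are log2 ratios of the 2 channels of each array. Limma is the tool named per the submitters' processing notes, and background correction, within-array normalisation and the spot filter are not given in the sources used here. Between 0.2 and 4 fold, 100% of the deposited log2 values corresponded to a ratio rounded to 0.01, within a tolerance of 0.002 (times the ratio where that is above 1). Near 4 fold that tolerance admits any value, so the 100% says nothing there. The 427382 values took only 961 distinct levels, and low ratios were coarsely graded. Array medians of the log2 values lay between -0.013 and 0.014, and array SDs between 0.261 and 0.771. Between 9893 and 19656 of the 32448 spots had a value on an array, and 11029 spots had none on any array. Signal intensities were not used here, so the precision of a value is limited by the number of arrays and extracts.

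The numerator of the ratio is not stated. It was taken as Cy5 over Cy3, which is likely because limma uses that convention and the array titles give the Cy5 state first. All signs would turn together if it were the opposite. On 29 arrays the state named first was in Cy5, and 1 array of the resistant control against infected plants at 7 dpi was labelled the other way. That array did not mirror its partner, so it could not be used to settle the direction (r = 0.127 across 7115 clones after turning its sign; clones are not independent replicates). For 1 of the 3 arrays that pair extracts of different numbers, the title and the source names give different extracts, and the source names were followed.

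The probe annotation pairs 1810 spots with genes of potato, so the probes were treated as potato clones hybridised with tomato RNA. The 2 spots of each annotated clone lay 844 (636 clones) or 1859 (269 clones) places apart in the numbering of spots. The layout rule read from this held for all 905 annotated clones and was applied to the others, which gave 15360 clones. The median correlation of the 2 spots across arrays was 0.958 for annotated clones, 0.848 for 5641 other clones and 0 for random pairs. The mean of a clone's spots was used. Of the clones, 815 carried 1 gene symbol, 90 carried several and were named by none, and 14455 had no symbol in the table used here. Of the 430 single symbols, 339 are locus numbers only and 91 have a lettered name. None of the 475 potato gene identifiers was in the tomato gene table used here, which gives 0 matches, so symbols are those of potato and no tomato coordinates are given. Cross-species hybridisation cannot separate closely related members of a gene family.

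All comparisons came from one model per clone over the whole network of arrays, with a term for each state and a term for the dye (10 parameters), and the extract as a random effect. The ratio of extract variance to array variance was 1.2, by restricted maximum likelihood pooled over 3752 clones with a value on every array. That ratio was applied to all clones and states, so no clone's own spread between extracts was measured separately. Across 5926 clones, the SD of the difference between a state's 2 extracts ran from 0.259 (susceptible mock, 3 dpi) to 0.653 (resistant mock, 3 dpi). A single ratio may thus be too large for some states and too small for others. The flipped-dye array was turned and averaged with its partner of the same extracts, which left 29 arrays. Clones needed at least 5 residual degrees of freedom, and 7536 were tested. Moderated tests used limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. All adjusted p-values given for clones are from limma. Errors are standard errors (SE) of log2 ratios from the fit, with 2 extracts per state. Spot pairing used Python 3.11.15 with pandas 2.3.3, and plots used matplotlib 3.10.9.

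The procedure was tested on simulated data with the real pattern of missing values and the estimated variances, in 5 runs of 7536 clones with 200 changed in each. In the simulated comparison of susceptible infected over mock plants at 7 dpi, 52.2% of 2-fold changes and 95.5% of 4-fold changes were called, and 4.3% of the calls were false. In the simulated comparison of resistant infected over mock plants at 3 dpi the corresponding values were 67.5%, 96.7% and 5%. In the simulated comparison of susceptible mock over control plants at 3 dpi they were 65.4%, 97.3% and 4.7%. Changes of 1.5 fold were called in 13.1%, 14.6% and 14% of cases in the same order. In 5 runs with no change, the highest number of calls in a comparison was 2. The data were drawn from the fitted model itself, with errors independent between clones and the same variance ratio in all states. These rates apply where that model holds, and they do not test it on the measured arrays.

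The states, the 16 comparisons, the alternatives and the rule for named genes were fixed before the data were examined. The rule took clones past the threshold whose sign was the same in replicate 1 alone and in replicate 2 alone, and from these the 10 highest and 10 lowest log2 ratios in infected over mock plants at both times and in the genotype comparisons of controls and of infected plants at 7 dpi, and the 4 highest and 4 lowest in the other comparisons, with 1 clone per symbol (lowest p). Where fewer than 5 clones passed, the 5 named clones with the lowest p are given as not past the threshold. Counting locus numbers as no name was decided after the annotation had been seen, and at most 2 loci that rose and 2 that fell are given per comparison. The 25 gene lists fixed beforehand search gene descriptions, and the annotation used here holds only symbols. No list reached 5 genes (the most was 2), so their planned tests were not run. Instead, 11 groups of symbols were written after the symbols, but no ratio of a named gene, had been seen. A gene counts as risen or fallen in a group if at least 1 of its clones was called. The 6 groups with at least 5 tested genes were compared with the 384 genes that have a symbol, using limma's cameraPR on 1 clone per gene (the clone with the most values), with a preset correlation of 0.01 and, beside it, an estimated one. Their p-values were adjusted over the groups of a comparison, and an adjustment over all 96 tests was added after seeing the data.

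Alternatives were a fit without the dye term, independent arrays, a replicate block, each replicate number left out, the 3 arrays of mixed numbers left out, extracts taken from the title, the flipped-dye array left out, arrays centred on their median, arrays scaled to one spread, only clones with a value on every array, and only the arrays that compared the states directly. With a replicate number left out, each state has 1 extract, and the variance ratio of 1.2 was taken over from the fit to all arrays. Calls in those fits rest on that ratio and on the spread between arrays, with no second extract to measure the spread between extracts.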

Results

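The arrays compared transcript levels in a susceptible and a resistant tomato genotype after inoculation with tomato yellow leaf curl virus (TYLCV), a DNA virus carried by whiteflies, with plants exposed to virus-free whiteflies as mock controls. The 30 hybridisations link 20 RNA extracts in 10 states, 2 extracts per state, so that each state is joined to others directly or through a chain of arrays. Between 5714 and 10368 clones had a value on an array, and 7536 were tested. Ratios are signed on the likely reading of the deposited values as log2 of Cy5 over Cy3. The tested clones include 130 that carry 78 lettered gene symbols, so most calls concern clones that are not named here.

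**Figure D1:**
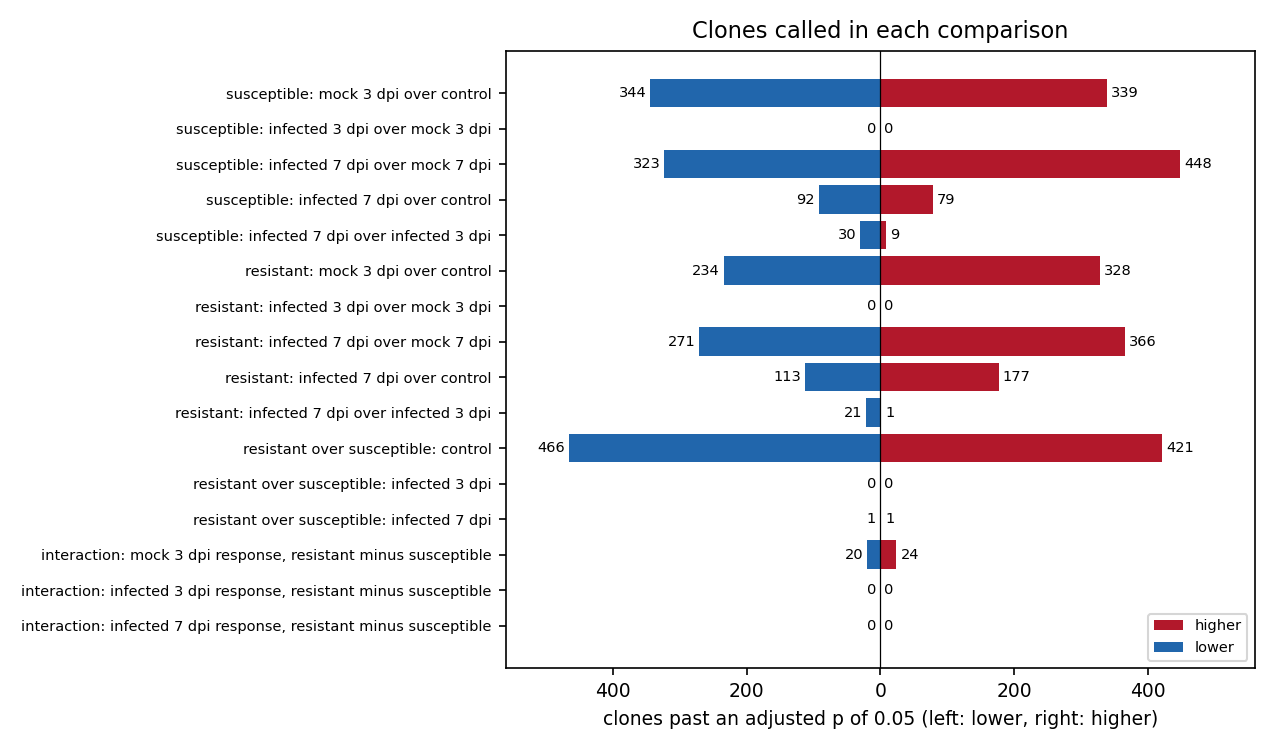
Number of clones past an adjusted p of 0.05 in each of the 16 comparisons (limma, 7536 clones, 2 extracts per state), with lower clones to the left and higher clones to the right of 0. Mock inoculation at 3 dpi, infection over mock at 7 dpi and the genotype difference in controls gave the most calls, and infection over mock at 3 dpi gave 0 in both genotypes.

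The first comparison sets mock plants, exposed to whiteflies without virus, at 3 dpi against controls. The labels do not say whether controls were caged, given insecticide or sampled at the same age, so the contrast is not of feeding alone. In susceptible plants, transcripts of PEST2, a pectinesterase of the cell wall, rose by 1.56 ± 0.37 (log2 ratio ± SE, adjusted p = 0.00904). PPO, a polyphenol oxidase that acts in wounded tissue, rose by 1.45 ± 0.25 (adjusted p = 0.000678), and both of its clones were called. DHAR, a dehydroascorbate reductase that regenerates ascorbate, rose by 1.30 ± 0.29, and PHA2, a plasma membrane proton ATPase, by 0.77 ± 0.23 in 1 of 3 clones. CO, a CONSTANS-type regulator of flowering, was lower at -2.45 ± 0.37 (adjusted p = 0.000227), as was FLS, a flavonol synthase, at -1.92 ± 0.37. PKIN1, a protein kinase, fell to -1.23 ± 0.20 and MIP2 to -1.01 ± 0.28. The call for FLS rested on 1 of its 4 clones, and the highest of the others read 0.71.

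Among groups of symbols in susceptible mock plants at 3 dpi, 2 of 6 redox and mitochondrial protection genes rose (DHAR and DHAR2, the latter by 0.55 ± 0.17). In the group of defence and wound response genes, 1 of 7 rose (PPO). In the group of hormone and developmental regulators, 2 of 7 fell, which were CO and the auxin response gene IAA3 (-0.66 ± 0.19). That group had a median log2 ratio of -0.353 and lay below the other genes with a symbol (cameraPR, adjusted p = 0.0312), which was not kept with an estimated correlation (adjusted p = 0.089). Of 96 tests of a group in a comparison, 3 passed when adjusted within a comparison, all of this group, and 0 when adjusted over all tests (cameraPR, lowest adjusted p = 0.0706). Of the unnamed loci, LOC102587499 and LOC102584296 rose by 2.39 and 2.38, and LOC102577576 and LOC102600559 fell to -5.24 and -2.26. In all, 683 clones were called, 339 higher and 344 lower (limma). The count was 1592 when arrays were treated as independent. It was 280 without replicate 2 and 97 without replicate 1, where each state has 1 extract and the extract variance is carried over from all arrays, as in all such counts below.

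Mock over control in resistant plants gave 562 called clones at 3 dpi, 328 higher and 234 lower. VPE2, a vacuolar processing enzyme (a cysteine protease), rose by 3.00 ± 0.86 (adjusted p = 0.0326), PEST2 by 1.57 ± 0.37, DHAR by 1.30 ± 0.29 and SI1 by 1.21 ± 0.26. CO fell to -1.55 ± 0.38, STUGE51 to -1.20 ± 0.28 and 16R to -0.92 ± 0.24 (1 of 2 clones each, the other 16R clone at 0.07), and NDPK1, a nucleoside diphosphate kinase, to -0.65 ± 0.15. The 2 extracts of resistant mock plants at 3 dpi differed most of all states (SD 0.653), so the SEs here may be too small. In replicates 1 and 2 alone VPE2 read 4.37 and 1.79 and CO -2.38 and -0.64, while SI1 read 1.19 and 1.30. In the group of glycolysis, fermentation and pyruvate entry, 2 of 8 genes rose, which were ADH1, an alcohol dehydrogenase (0.91 ± 0.24), and LPD2, a dihydrolipoamide dehydrogenase (0.93 ± 0.18). In the defence and wound response group 2 of 7 rose, HPL, a hydroperoxide lyase of oxylipin synthesis (0.91 ± 0.22), and VPE2. The group test did not pass (adjusted p = 0.135, cameraPR). Of the pump and channel group, 2 of 4 genes rose, PHA2 (0.82 ± 0.23) and the potassium channel gene SKT3 (1.17 ± 0.31). Of the unnamed loci, LOC102596783 and LOC102602308 rose by 2.13 and 2.10, and LOC102577576 and LOC102591352 fell to -3.60 and -1.56. The count was 258 without replicate 2, 92 without replicate 1, 982 on direct arrays only and 1375 with independent arrays. With arrays scaled to one spread the calls for STUGE51 and LOC102577576 were lost.

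The mock over control responses of the genotypes had 104 higher and 64 lower calls in common, where independent lists would share 14.8 and 10.7. Their log2 ratios had r = 0.521 across 7536 clones, which are not independent replicates. Simulated data without any effect gave r = 0.086, where the estimates are joined only by the common fit. Errors were simulated independently for each clone, so this value leaves out errors shared by many clones. It is no full measure of r without effect. The corresponding covariances were 0.129 observed and 0.00648 without effect. The difference between the genotypes was tested as an interaction and passed for 44 clones (24 higher and 20 lower in resistant plants). PPO responded less in resistant plants by a log2 difference of -1.48 ± 0.35 (adjusted p = 0.0484, 1 of 2 clones), since its ratio there was -0.03 ± 0.25. GAPDH, the glycolytic glyceraldehyde-3-phosphate dehydrogenase, differed by -0.71 ± 0.16 (adjusted p = 0.0484) in 1 of 8 clones. The loci LOC102577840, LOC102582711 and LOC102601848 differed by 1.85, -1.15 and -0.96. The count was 19 with the replicate block, 7 without a dye term, 94 without the flipped-dye array and 904 with independent arrays. It was 14 with arrays scaled to one spread (11 higher, 3 lower), and the calls for PPO and GAPDH were lost there, without a dye term, with the replicate block and without the mixed-number arrays, and that for PPO also on direct arrays only.

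Infection over mock at 3 dpi addresses the early response to the virus, with both sides exposed to whiteflies. No clone passed the limma threshold in either genotype, with 206 clones in susceptible and 466 in resistant plants at an unadjusted p under 0.05, where 377 of 7536 would be found by chance. The 206 in susceptible plants, and the 55 in the interaction below, lie under 377. A variance ratio too large for these states would give such counts, which was not tested. The 0 calls thus do not show that an early response was absent. In resistant plants the lowest p among lettered symbols belonged to MS, a methionine synthase, at 0.74 ± 0.18 (adjusted p = 0.157). The 4 other MS clones read between 0.63 ± 0.23 and 0.92 ± 0.26. PPO read 0.93 ± 0.25 (adjusted p = 0.22), NAC2, a NAC-type regulator, -0.96 ± 0.29, CDPK2, a calcium-dependent protein kinase, 0.47 ± 0.17, and STWRKY8, a WRKY-type regulator, -0.89 ± 0.37. In susceptible plants METK1, an S-adenosylmethionine synthetase, read -0.47 ± 0.20, DD 0.37 ± 0.18, GAPDH 0.21 ± 0.12, RANGAP2 -0.72 ± 0.39 and ERS, an ethylene receptor, -0.40 ± 0.23, all with an adjusted p of 1. In resistant plants 19 clones were called on direct arrays only, 9 without a dye term and 95 with independent arrays. The interaction gave 0 calls (limma, 55 clones at an unadjusted p under 0.05) with METK1 at 0.68 ± 0.27, STUGE51 at -0.84 ± 0.38, MS at 0.70 ± 0.33, PKIN1 at -0.59 ± 0.28 and PPO at 0.70 ± 0.35.

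At 7 dpi, infected over mock plants addresses the later response to the virus, but the ratio holds changes of either side. In susceptible plants 829 clones were called between mock plants at 7 dpi and controls, and 171 between infected plants and controls (limma). In resistant plants these counts were 15 and 290. The mock counts were added after seeing the data. None of the lettered genes named in this paragraph was called in susceptible infected plants at 7 dpi over controls. In susceptible plants VPE2 rose by 3.82 ± 0.93 (adjusted p = 0.00884), RSI5 by 2.87 ± 0.65, DHAR by 1.89 ± 0.31 (adjusted p = 0.000279), GBSS, the granule-bound starch synthase that makes amylose, by 1.22 ± 0.29, SI1 by 1.16 ± 0.26, METK1 by 0.88 ± 0.20 and DE2 by 0.44 ± 0.14. Lower transcripts with lettered symbols were STUGE51 at -1.32 ± 0.30, PPO at -1.02 ± 0.29 (1 of 2 clones), MIP2 at -0.996 ± 0.31, DD at -0.85 ± 0.20, 16R at -0.84 ± 0.27 (1 of 2 clones), PKIN1 at -0.69 ± 0.22 and TS at -0.61 ± 0.20. Of the group of methionine and other amino acid genes 1 of 5 rose (METK1, in 4 of its 9 clones), and of starch and sucrose genes 1 of 6 rose (GBSS) and 1 fell (PKIN1). PSBR, a subunit of photosystem II, rose in 1 of 5 clones by 1.59 ± 0.44, and the lowest of its clones read -0.13. In all, 771 clones were called, 448 higher and 323 lower (limma). Fewer were called with arrays scaled to one spread (293), without replicate 1 (301) and without replicate 2 (87), and more without a dye term (1234) and on direct arrays only (1444). With arrays scaled to one spread, only VPE2, RSI5 and DHAR of the lettered genes listed first stayed past the threshold, and the 11 others kept their sign. LOC102577576 and LOC102577514 were lost as well. The loci LOC102584296 and LOC102596783 rose by 2.94 and 2.66, and LOC102577576 and LOC102577514 fell to -3.74 and -2.23.

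In resistant plants at 7 dpi, infection over mock gave 637 calls, 366 higher and 271 lower. RSI5 rose by 3.01 ± 0.65 (adjusted p = 0.00589), DHAR by 1.45 ± 0.31, METK1 by 1.28 ± 0.20 (adjusted p = 0.000326, 7 of 9 clones called), GBSS by 1.24 ± 0.26, SI1 by 1.03 ± 0.26, HPL by 1.02 ± 0.24, GAPDH by 0.89 ± 0.25 (2 of 8 clones called, the lowest at -0.18), HRBP1 by 0.77 ± 0.20 and LPD2 by 0.62 ± 0.20. FLS rose by 1.39 ± 0.37 in 1 of 4 clones, while another of its clones read -1.02 ± 0.41. STUGE51 at -1.31 ± 0.30 (1 of 2 clones), PPO at -1.11 ± 0.27 and NDPK1 at -0.54 ± 0.17 were lower. In the group of glycolysis, fermentation and pyruvate entry, 3 of 8 genes rose (GAPDH, ADH1 and LPD2, with ADH1 at 1.20 ± 0.27), and in the redox group 2 of 6 (DHAR and DHAR2). The loci LOC102602308 and LOC102596783 rose by 3.27 and 3.02, and LOC102577514 and LOC102590882 fell to -2.48 and -1.79. The count was 162 with arrays scaled to one spread, 237 without replicate 1, 8 without replicate 2, 1041 without a dye term and 1293 on direct arrays only. With arrays scaled to one spread, RSI5, METK1, LOC102602308, LOC102596783 and LOC102590882 stayed past the threshold, and DHAR, FLS, GBSS, SI1, HPL, GAPDH, HRBP1, LPD2, STUGE51, PPO, NDPK1 and LOC102577514 did not. The 4 mock arrays at 7 dpi are the only ones that hold these mock extracts, so no other array checks their orientation.

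The infection responses of the genotypes at 7 dpi had 242 higher and 151 lower calls in common, where independent lists would share 21.8 and 11.6. The correlation was 0.817 across 7536 clones, against 0.142 in simulated data without effect, and the covariances were 0.295 and 0.0131. The simulated errors were independent between clones, so the values without effect leave out errors shared by many clones. The interaction gave 0 calls (limma, 2 with independent arrays). At an unadjusted p under 0.05 there were 218 clones, where 377 would be found by chance. The p-values may thus be too high, and the 0 calls do not show equal responses. Among lettered symbols the lowest p values belonged to STWRKY8 at -1.41 ± 0.55, ADH1 at 0.89 ± 0.31, EI2 at 0.65 ± 0.26, GAPDH at 0.60 ± 0.26 and XIP1-1-BETA at 0.90 ± 0.38, all with an adjusted p of 0.999.

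**Figure D2:**
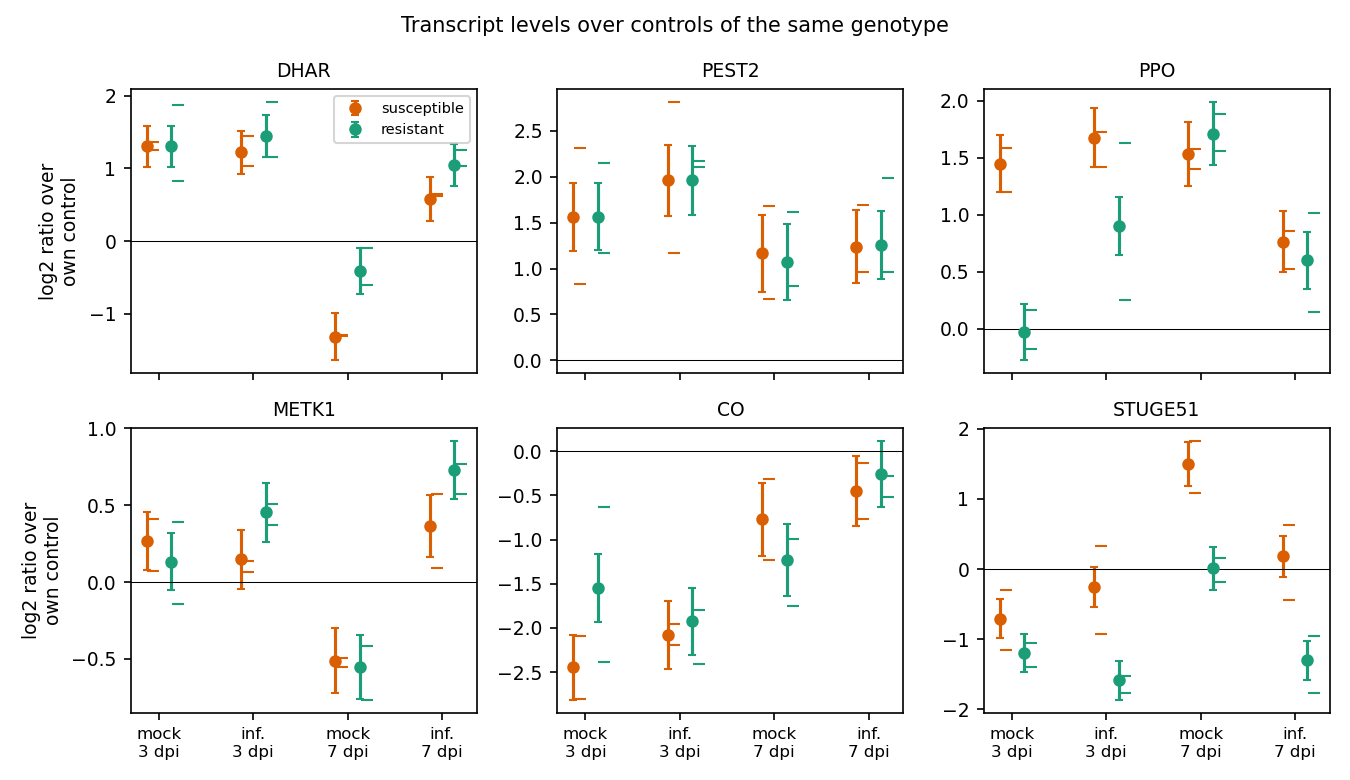
Log2 ratio of mock and infected plants at 3 and 7 dpi over controls of the same genotype for 6 genes picked from those named by the rule after their values were seen (1 clone each). Circles are the estimates from all arrays with SE, and dashes are the fits of replicate 1 and of replicate 2 alone. DHAR stood at 1.30 in mock plants of both genotypes at 3 dpi and at -1.32 in susceptible and -0.41 in resistant mock plants at 7 dpi, while PEST2 lay above 0 in every state shown.

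Infected plants at 7 dpi were also set against controls. In susceptible plants GAPDH was higher by 0.70 ± 0.19 (adjusted p = 0.047) in 1 of 8 clones and FLS lower at -1.84 ± 0.40 (adjusted p = 0.0143) in 1 of 4 clones, LOC102584296 and LOC102577558 were higher by 2.40 and 2.28, and LOC102605379 and LOC102582373 lower at -1.36 and -1.27. In resistant plants FLS was higher by 1.30 ± 0.35 in another clone, SI1 by 1.05 ± 0.26 (2 of 3 clones), DHAR by 1.04 ± 0.29 and HPL by 0.84 ± 0.22 (1 of 2 clones), and STUGE51 was lower at -1.30 ± 0.28 in both of its clones. METK1 was higher by 0.73 ± 0.19 in resistant plants in 1 of 9 clones. There LOC102602308 and LOC102584296 were higher by 2.42 and 2.15, and LOC102577576 and LOC102591352 lower at -3.36 and -1.71. The counts were 171 in susceptible plants (79 higher, 92 lower) and 290 in resistant plants (177 higher, 113 lower; limma). Leaving out the flipped-dye array, which compares the same resistant states, raised them to 467 and 1054, and they fell to 36 and 138 without replicate 1, and in resistant plants to 4 without replicate 2. Of the 1054 calls in resistant plants without the flipped-dye array, 459 were higher and 595 lower, so the majority turned. Arrays scaled to one spread gave 12 calls in susceptible plants (4 higher, 8 lower) and 168 in resistant plants. The calls above for FLS, SI1, DHAR, HPL, STUGE51 and LOC102577576 in resistant plants and for GAPDH, FLS, LOC102584296, LOC102605379 and LOC102582373 in susceptible plants were lost there.

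From 3 to 7 dpi in infected plants, CO rose by 1.63 ± 0.37 in susceptible plants (adjusted p = 0.0371) and by 1.67 ± 0.37 in resistant plants (adjusted p = 0.0458). Hormone and developmental regulators lay above the other genes with a symbol in both, with median log2 ratios of 0.475 (cameraPR, adjusted p = 0.00484) and 0.245 (adjusted p = 0.00884). Both passed with an estimated correlation (adjusted p = 0.0208 and adjusted p = 0.0333), and neither when adjusted over all 96 tests (adjusted p = 0.0706). Within that group CO alone, 1 of 7 genes, passed the test for single clones, and NAC2 read 0.75 ± 0.29 and 0.66 ± 0.29, IAA3 0.48 ± 0.19 and 0.41 ± 0.19, and ERS 0.60 ± 0.23 and 0.25 ± 0.22. In susceptible plants 39 clones were called, 9 higher and 30 lower, and in resistant plants 22, of which 21 were lower, among them LOC102605062 at -1.04 ± 0.20 and LOC102587698 at -0.94 ± 0.18. LOC102601725 rose by 0.94 ± 0.17 in susceptible plants. The counts ranged from 4 to 551 and from 1 to 69 over the alternatives. The call for CO was lost in both genotypes without the arrays of mixed numbers and on direct arrays only. It was also lost in resistant plants without a dye term, with the replicate block and without the flipped-dye array.

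The genotypes were compared within controls and within infected plants. In controls the resistant genotype had higher STUGE51 (2.06 ± 0.29, adjusted p = 0.000108, both clones called), MIP2 (0.96 ± 0.29), PURM (0.91 ± 0.17), GAPDH (0.59 ± 0.12, 1 of 8 clones) and NDPK1 (0.58 ± 0.16). It had lower PSBR (-1.38 ± 0.32, 3 of 5 clones called), FLS (-1.24 ± 0.36, 1 of 4 clones), SI1 (-1.12 ± 0.23), GBSS (-1.04 ± 0.28), BEL5, a homeobox regulator (-0.96 ± 0.26, 1 of 2 clones), HPL (-0.82 ± 0.24), LPD2 (-0.80 ± 0.19) and HRBP1 (-0.64 ± 0.19). In the group of glycolysis, fermentation and pyruvate entry 1 of 8 genes was higher (GAPDH) and 2 were lower (ADH1, at -1.12 ± 0.27, and LPD2). The loci LOC102591352 and LOC102577446 were higher by 1.83 and 1.62, and LOC102589208 and LOC102602308 lower at -2.62 and -2.05. In all, 887 clones were called, 421 higher and 466 lower (limma). The count was 39 without replicate 1, 186 without replicate 2, 408 with arrays scaled to one spread, 1835 with independent arrays and 1961 on direct arrays only, and MIP2, FLS, SI1, HPL, LPD2 and HRBP1 were not past the threshold without a dye term. With arrays scaled to one spread the calls for MIP2, NDPK1, PSBR, FLS, GBSS, BEL5, HPL and HRBP1 were lost.

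In infected plants at 3 dpi no clone passed (limma, 630 at an unadjusted p under 0.05). The genotype ratio there had r = -0.308 between replicates 1 and 2 across 5538 clones. The extracts thus disagreed, and the 0 calls do not show that the genotypes were alike. Among lettered symbols the lowest p values were those of AOX, the mitochondrial alternative oxidase (0.87 ± 0.32), PSBR (-0.81 ± 0.31), STUGE51 (0.73 ± 0.28), PKIN1 (0.46 ± 0.20) and LPD2 (-0.40 ± 0.18), with adjusted p between 0.491 and 0.565. Independent arrays gave 154 calls and direct arrays only 145. In infected plants at 7 dpi 2 clones were called, among them LOC102589608 at -1.05 ± 0.19 (adjusted p = 0.0496). METK1 read -0.61 ± 0.23, AOX 0.74 ± 0.32, PURM 0.36 ± 0.16, R1 -0.33 ± 0.16 and STUGE51 0.58 ± 0.28, none past the threshold. At an unadjusted p under 0.05 there were 253 clones, where 377 would be found by chance, so these p-values may be too high. With independent arrays 10 clones were called. The call for LOC102589608 was lost with arrays scaled to one spread, with arrays centred on their median and without the mixed-number arrays.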

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

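The tests of other extracts on the flipped-dye array, of dye bias in the genotype and 7 dpi patterns, of mock plants near controls, of mock arrays run opposite to their labels and of the genotype difference between states were chosen only after the result was seen. For mock plants at 7 dpi, bounds on the profile share alone were replaced by bounds on share and count after the values were seen, and the bound for other extracts on the flipped-dye array was loosened after its value was seen. The following results are listed because an effect differed between genotypes or states in a test of the difference itself. The mock over control response at 3 dpi differed between the genotypes in 44 clones, with log2 differences (resistant minus susceptible) of -1.48 for PPO, -0.71 for GAPDH, 1.85 for LOC102577840, -1.15 for LOC102582711 and -0.96 for LOC102601848. The genotype difference in controls differed from that in infected plants at 7 dpi in 12 clones and from that in infected plants at 3 dpi in 49. The last 2 comparisons were added after seeing the data. Without the flipped-dye array the counts were 93 and 141.

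The genotypes differed in 887 clones in controls and in 2 in infected plants at 7 dpi, and in 0 in mock plants at 3 and at 7 dpi (limma, 840 and 400 at an unadjusted p under 0.05; added after seeing the data), which no array compared directly. A single deviating control extract is argued against: the covariance of the genotype ratio between replicates 1 and 2, which share no extract, was 9.2 times as large in controls as in infected plants at 7 dpi (95% bootstrap interval over clones 7.38 to 11.7). That interval leaves out the spread between extracts, which is wider: the covariance was 0.18 in controls, 0.0196 in infected plants at 7 dpi and -0.0807 in infected plants at 3 dpi, so the ratio itself is not precise. Dye bias is argued against as the whole cause, since the susceptible extract was in Cy5 on all direct arrays of both comparisons, and without a dye term 728 clones were called in controls and 2 in infected plants at 7 dpi. The 0 calls in mock plants do not show that the genotypes were alike there. The 2 resistant mock extracts differed with an SD of 0.653 at 3 dpi and 0.527 at 7 dpi across clones. Extracts that disagree give few calls in any case, so these counts neither tie the pattern to the virus nor separate it from the virus. Whether whitefly exposure, insecticide, handling or age of the plants goes with the pattern stays open, as the labels do not state these for the controls.

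The infected over mock ratio at 7 dpi resembled the mock over control ratio at 3 dpi: single arrays of the 2 comparisons, which share no extract, correlated across clones with a median r of 0.435 (0.351 to 0.686 in 16 pairs of arrays, both genotypes), and the fitted ratios, which are joined by other arrays, with 0.425 in susceptible and 0.575 in resistant plants (0.098 and 0.077 in simulated data without effect). The simulated errors were independent between clones, so the values without effect leave out errors shared by many clones. Dye bias is argued against as the whole cause, since its variance was 0.115 of the mean covariance of the arrays concerned. One possible explanation is that mock plants were near the control state at 7 dpi while infected plants kept the 3 dpi mock profile. In resistant plants the values went with this: 15 clones were called between mock plants at 7 dpi and controls. The shares of the 3 dpi mock profile were -0.17 in mock and 1.19 in infected plants. By the profiles of replicates 1 and 2 they were 0.138 and -0.479 in mock, where the sign turned, and 1.829 and 0.552 in infected plants. However, the resistant mock over control ratios at 7 dpi had r = 0.049 between replicates 1 and 2. The difference between the 2 resistant mock extracts had an SD of 0.527 across clones. Extracts that disagree give few calls in any case, so the 15 calls do not show that these mock plants were near controls. In susceptible plants 829 clones were called between mock plants at 7 dpi and controls, so mock plants were not near controls there, with shares of -0.162 and 0.524. If the 4 mock arrays at 7 dpi ran opposite to their labels, the shares in mock plants would be 1.21 in susceptible and 2.55 in resistant plants; the first is close to the 3 dpi profile and the second is not, and no other array holds these extracts, so this cannot be told apart from the labelled orientation.

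The flipped-dye array of resistant controls against infected plants at 7 dpi did not mirror its partner: after turning its sign r was 0.127, where the 2 unflipped arrays of this comparison had r = 0.685. Dye bias is argued against, because the departure of the array from the ratio fitted without it had an SD of 0.68, the dye term had an SD of 0.15, and their correlation was -0.375, although error shared by both pulls that value down. Noise alone is argued against by the correlation of 0.636 between the 2 spots of a clone on this array, above the lowest of the other arrays (0.566). Other extracts than the labels give stay a candidate explanation: the best match among pairs of extracts was susceptible infected over mock at 3 dpi (number 2) with r = 0.507, against 0.099 for the labelled pair, and this cannot be told apart from an extract outside the series. No biological explanation was tested, as both arrays are labelled with the same extracts.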

How the results depend on the processing

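Of 102 results for named clones past the threshold, 0 reversed under the alternatives that keep both replicates (100 of them had a value on direct arrays only, and 70 among clones on every array). The number no longer past it was 52 with arrays scaled to one spread, 22 without the mixed-number arrays, 14 without a dye term, 7 on direct arrays only, 6 with the replicate block, 4 with independent arrays, 2 with arrays centred, 1 without the flipped-dye array, and 0 with extracts from the title and among clones on every array. Array SDs ran from 0.261 to 0.771, and scaling to one spread narrows the ratios of wide arrays and widens those of narrow ones. Ratios then need not add up around a loop of arrays, as the model assumes, so calls lost there may come from the scaling itself. Named clones were chosen as past the threshold and for one sign in each replicate alone, so their sign says nothing with a replicate left out. The alternatives that keep both replicates refit mostly the same arrays, so the 0 reversals there are no independent check. Of all calls, 2 of 829 between genotypes in controls reversed without replicate 1. Among results not past it, NAC2 in resistant infected over mock plants at 3 dpi ranged from -1.92 to 0.10 and PKIN1 between infected genotypes at 3 dpi from -0.17 to 1.065 when a replicate was left out, so each reversed once (NAC2 without replicate 1, PKIN1 without replicate 2). The cause was not tested. Leaving out a replicate leaves 1 extract in every state, and these are assumed to vary as in all arrays together (variance ratio 1.2), so counts in those fits do not measure the spread between extracts.

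Below, S and R stand for susceptible and resistant plants, and counts beyond 1.5 times the value in the report are given by setting. With replicates left out, the ranges were 97 to 280 (S) and 92 to 258 (R) for mock over control at 3 dpi, 1 to 8 (S) and 0 to 28 (R) for infected over mock at 3 dpi, 87 to 301 (S) and 8 to 237 (R) for infected over mock at 7 dpi, 36 to 126 (S) and 4 to 138 (R) for infected at 7 dpi over control, 4 to 16 (S) and 1 to 10 (R) for infected at 7 over 3 dpi, 39 to 186, 16 to 97 and 0 to 0 for the genotypes in controls and in infected plants at 3 and 7 dpi, and 2 to 8 for the interaction in mock plants. Independent arrays gave 1592 (S) and 1375 (R) for mock over control, 95 (R) for infected over mock at 3 dpi, 427 (S) and 821 (R) for infected at 7 dpi over control, 551 (S) and 69 (R) for infected at 7 over 3 dpi, 1835, 154 and 10 for the genotypes, 904 for the interaction in mock plants and 2 for that at 7 dpi. Without a dye term the counts were 1234 (S) and 1041 (R) for infected over mock at 7 dpi, 448 (S) and 689 (R) for infected at 7 dpi over control, 9 (R) for infected over mock at 3 dpi and 7 for the interaction in mock plants. Arrays scaled to one spread gave 293 (S) and 162 (R) for infected over mock at 7 dpi, 12 (S) and 168 (R) for infected at 7 dpi over control, 137 (S) for infected at 7 over 3 dpi, 408, 4 (3 higher, 1 lower) and 0 for the genotypes and 14 for the interaction. Direct arrays only gave 982 (R) for mock over control, 19 (R) for infected over mock at 3 dpi, 1444 (S) and 1293 (R) for it at 7 dpi, 886 (S) and 765 (R) for infected at 7 dpi over control, 107 (S) and 13 (R) for infected at 7 over 3 dpi, and 1961 and 145 for the genotypes in controls and at 3 dpi. Without the flipped-dye array, infected at 7 dpi over control gave 467 (S) and 1054 (R), the genotypes at 7 dpi 1 and the interaction 94. Extracts from the title gave 60 (S) for infected at 7 over 3 dpi and 9 (R) for infected over mock at 3 dpi. Clones on every array gave 75 (S) for infected at 7 over 3 dpi and 110 for the interaction. Without the mixed-number arrays the interaction gave 17 and the genotypes at 7 dpi 0, as did centred arrays for the latter.

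Whether the replicate numbers pair the extracts was not settled. The difference between numbers 1 and 2 correlated over 0.1 in 31 of 45 pairs of states. Extracts of numbers 1 and 2 are joined only through the 3 arrays of mixed numbers, so all these differences share the error of those arrays, which can raise their r. The lowest r was -0.394, the median 0.176 and the highest 0.638. The replicate block moved the interaction in mock plants from 44 to 19 and no other count beyond 1.5 times. The block term acts only on the 3 arrays of mixed numbers, so it could move little and does not test whether the numbers pair the extracts. Turning the direction of every ratio turns all signs and no count. Shifts of the gene lists were not tested, as no list had 5 genes. Signal over background was not used here, so limits for dim clones are unknown.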

Other observations

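Values that fall outside the comparisons of the report concern mock plants at 7 dpi over controls, which were added after seeing the data. PPO stood 1.54 ± 0.28 (adjusted p = 0.000904, limma) above controls in susceptible and 1.71 ± 0.28 (adjusted p = 0.00484) above controls in resistant mock plants at 7 dpi, and at 0.76 ± 0.27 and 0.60 ± 0.25 in infected plants, not past the threshold. STUGE51 stood at 1.497 ± 0.31 (adjusted p = 0.00297) in susceptible and 0.01 ± 0.31 in resistant mock plants at 7 dpi, and DHAR at -1.32 ± 0.32 (adjusted p = 0.0109) and -0.41 ± 0.32. These values rest on the labelled orientation of the 4 mock arrays.

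The genotype ratio in infected plants at 3 dpi had r = -0.308 between replicates 1 and 2 across 5538 clones, against 0.458 in controls and 0.209 in infected plants at 7 dpi. Closed loops of arrays with as many arrays on both paths should sum to 0 apart from error. They had r between 0.588 and 0.863 between their 2 paths across clones. Loops that set 3 arrays against 1 also keep the dye terms of the extra arrays, and they had r between 0.735 and 0.871. The flipped-dye array was not among the loops.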
